A study of Mus musculus with 6 samples.

How the data were processed

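Total RNA from mouse sciatic nerve at postnatal day 14 was hybridised to Mouse WG-6 version 2 bead arrays, 1 array per sample. There were 3 arrays of nerves from mice carrying the P0-Cre transgene and a Dicer mutation and 3 arrays of control littermates. The genotype label of the mutants adds "F or N" after Dicer, which is not explained in the sources used here, so which Dicer allele or alleles each mutant array holds is not known. The series' design text speaks of tissue-cultured cells, while its title and every sample label name sciatic nerve, which is followed here. Per the labels' protocols, the nerves were fresh frozen, homogenised in lysis buffer and extracted with phenol and chloroform, and the RNA was recovered on a filter. Both sexes are named for every sample, and whether each array held 1 animal or a pool is not given in the sources used here. The p-values of single probes therefore measure the spread between these 6 samples, which may be partly technical.

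The deposited values are on a log2-like scale and run from 7.96 to 15.91. Per the labels, that is the series' design text, limma was used and the data were normalized by RMA. The submitters' processing notes name lumi 1.8.3. Whether the scale is plain log2 or the variance-stabilising transform of lumi is not settled by these sources, so changes are given as differences on the deposited scale. On a variance-stabilised scale a difference among dim probes would understate the log2 fold change. The 6 columns hold the same distribution: their medians are all 8.24, and their sorted values differ by at most 0.00025. Background correction is not given in the sources used here.

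The design text states a filter on present and absent calls that kept 18420 of 45281 probes. No such calls were used here. In their place the 18420 probes with the highest mean over all 6 arrays were kept, whatever their group, and the other 26861 were left out. The lowest mean among the kept probes was 8.34, close to the median of 8.24 of all probes, so many kept probes lie near the dim end of the scale. No further normalization was applied.

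Probes were named from the platform annotation supplied with the data. Of the 45281 probes, 34885 had 1 gene symbol, 18 had several and 10378 had none, and among the kept probes these numbers were 15837, 6 and 2577. Gene identifiers of 34807 probes matched the RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed by that match. No coordinates are printed. Probes with several symbols or none were tested but not named. Where a gene had several kept probes, which was so for 3834 genes, the probe with the highest mean over all arrays represented it. Of the genes tested, 1104 had both called and uncalled probes, and 24 had probes called in opposite directions.

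Mutant and control arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, with 4 residual degrees of freedom and 2.63 prior degrees of freedom). P-values were adjusted by Benjamini-Hochberg over the kept probes, and a probe was called at an adjusted p under 0.05. The 2-fold threshold of the design text was applied as a difference of at least 1 on the deposited scale. Gene lists were compared with camera at a preset correlation of 0.01, on 1 probe per gene, with Benjamini-Hochberg adjustment over the 28 lists that had at least 3 measured members. At that preset, a list's p-value takes its degrees of freedom from the number of genes and not of arrays. A very small one therefore does not measure the spread between samples. The number of arrays limits the precision of every value.

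The tests, the gene lists and the rule for named genes were fixed before the data were examined. The rule names Dicer1, the 15 genes with the largest rise and the 15 with the largest fall among those called at least 2-fold with separated groups, and up to 4 called members of each list. Where a list had no called member, its 2 brightest members are named, and every member is named where 3 or fewer were measured. Probes with no single symbol or with a clone or locus name were passed over, 1 among the rises and 5 among the falls. The rule gave 116 genes. Further genes named as examples are members of the fixed lists, or are said to have been chosen after their values were seen.

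The steps were tested on simulated data for the comparison of mutant with control, with 18420 probes. Of 50 probes changed by 0.3 on the log2 scale, 14% were recovered, and of 50 changed by 0.5, 68% were. All 50 probes changed by 1 and all 50 changed by 2 were recovered. Of 145 probes called in the simulation, 4 were unchanged, and 0 of 29 unchanged lists were called. With 145 probes called here against 6596 in the data, an adjusted p under 0.05 asked for a smaller unadjusted p than in the data. The shares recovered therefore do not apply to the real comparison. The probes were simulated independently of each other, so the simulation does not test camera on lists whose genes are correlated.

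The sample titles carry the same replicate numbers in both groups. Over the kept probes, deviations from the group means correlated at 0.165, 0.155 and 0.224 for the arrays that share a number, and at -0.157 to 0.028 for the other pairs of a mutant with a control array. All 3 same-numbered pairs lie above 0.1, so the numbers may pair the samples, though no litter or batch is stated. The deviations cancel out within each group, so these correlations depend on each other and the check does not settle a pairing. The comparison itself had no block, since the design text names none. The value with replicate number as a block is given beside a result where it changes the call or a count by more than 1.5 times.

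The alternatives tried were no filter and a stricter filter on brightness, other normalizations, an offset, an intensity trend, array weights, the replicate block, another fold threshold, other set tests, and leaving out each array. Cyclic loess, the ribosomal protein and muscle marker medians as covariates, and counts of list members and of other gene groups without single arrays were added after the data were seen.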

Results

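Gene expression was measured in sciatic nerves of 14-day-old mice, an age at which Schwann cells, the glia of peripheral nerve, are building myelin. The mutants carry Cre recombinase under the promoter of P0, the main protein of peripheral myelin, together with a Dicer mutation, whose genotype label names 2 alternatives (F or N) that the sources used here do not explain. Dicer is the enzyme that cuts microRNA precursors to their mature length. There were 3 arrays of mutant nerves and 3 of control littermates, each with 45281 probes, of which the 18420 brightest were tested. Values are normalized signals on a log2-like scale whose exact transform is not settled, and every difference below is mutant minus control on that scale. Over the tested probes, correlations between arrays were 0.992 to 0.995 among the control arrays, 0.973 to 0.993 among the mutant arrays and 0.912 to 0.942 between the groups. The first principal component held 80.7% of the variance and parted the groups, and the second, with 11.7%, set mutant replicate 1 apart from the other mutant arrays.

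The design asks how the nerve transcriptome of P0-Cre Dicer mutants differs from that of control littermates. In the mutant nerves, 19 of 21 measured myelin protein genes and all 18 of cholesterol synthesis fell. Of 16 genes of immature and non-myelinating Schwann cells, 14 rose and 1, Scn7a, fell. In the injury response 8 of 12 measured genes rose, and in the cell cycle 25 of 26. camera called these 5 lists, but with an estimated correlation only the cell cycle list was called (adjusted p = 0.0361), and the adjusted p of the other 4 ran from 0.0774 to 0.144. Ncmap, a protein of noncompact myelin, fell most among the named genes, from 14.45 ± 0.088 in controls to 9.45 ± 0.367 in mutants (SD, n = 3 each). Ngfr, the low-affinity neurotrophin receptor carried by immature Schwann cells, rose from 10.50 ± 0.106 to 13.92 ± 0.111. The myelin transcription factor gene Egr2 fell from 13.06 ± 0.178 to 10.60 ± 0.057, while Sox10, which marks the Schwann lineage, stood at 13.94 ± 0.023 in controls and 13.98 ± 0.119 in mutants.

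**Figure D1:**
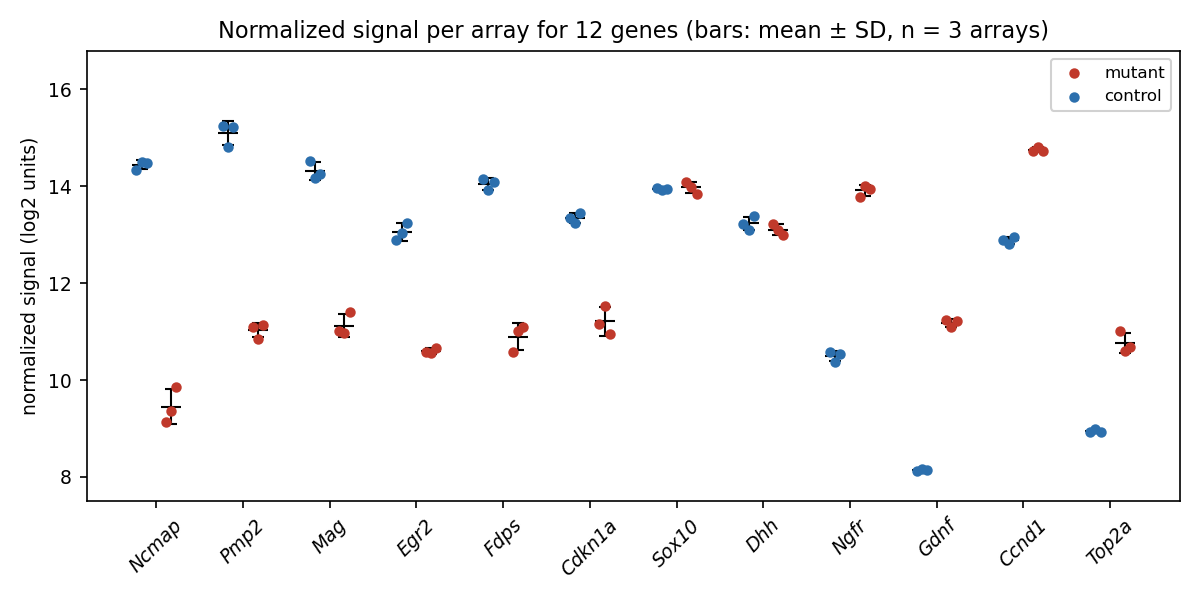
Normalized signal on the log2-like scale (vertical axis) of 12 genes in each of 3 control arrays (blue) and 3 mutant arrays (red), with black bars for the mean and SD of each group. Ncmap, Pmp2, Mag, Egr2, Fdps and Cdkn1a are lower in every mutant array, Ngfr, Gdnf, Ccnd1 and Top2a are higher, and the groups of Sox10 and Dhh overlap.

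The change reached a large part of the tested transcriptome. limma called 6596 of the 18420 probes (35.8%) at an adjusted p under 0.05, of which 3664 were higher and 2932 lower in mutants. With the added threshold of 2-fold, 828 probes were called, 378 higher and 450 lower, and 92 of them carry no single gene symbol. Counted by the brightest probe of each gene, 4068 of 10273 genes were called, and 572 of them at least 2-fold, 271 higher and 301 lower. As follows largely from how they were chosen, all mutant arrays lay beyond all control arrays in 827 of the 828 probes called 2-fold. Among all tested probes this share was 52.1%, where chance gives 10%.

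Dicer1, the gene named in the genotype, was read by 2 probes. The brighter had 9.17 ± 0.0996 in mutants and 9.19 ± 0.0845 in controls, a difference of -0.02 (SE 0.073, limma adjusted p = 0.832). The dimmer lay near the low end of the scale, at 8.39 ± 0.0565 and 8.59 ± 0.0824, and fell by 0.20 (SE 0.063, adjusted p = 0.0458). Its call was lost with the replicate block (adjusted p = 0.0529), without filtering (0.0558) and without any of 5 single arrays: mutant replicate 1 (0.0602), 2 (0.0634) or 3 (0.113), or control replicate 1 (0.15) or 2 (0.137). Where either probe lies relative to the deleted part of the gene is not known here, so neither probe checks the genotype labels.

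The 15 genes with the largest rise were led by Crabp1, a retinoic acid binding protein, at 4.55 (SE 0.222), and the keratin gene Krt23 at 4.38 (SE 0.083). Alox5, the 5-lipoxygenase of leukotriene synthesis, rose by 3.50 (SE 0.069), followed by Ngfr at 3.42. The matrix glycoprotein gene Tnc rose by 3.09, the cadherin gene Cdh6 by 3.09 and the neurotrophic factor gene Gdnf by 3.04 (SE 0.059). Smoc1, Kcnh2, Gfra3, Npy5r, Parp14, Col18a1, Minar2 and Sfrp1 rose by between 2.46 (Sfrp1) and 3.01 (Smoc1). Gfra3 encodes a co-receptor for a relative of Gdnf, Kcnh2 a potassium channel, and Sfrp1 a secreted regulator of Wnt signalling. For these 15 genes the limma adjusted p ran from 2.42e-06 (Krt23, Alox5 and Gdnf) to 1.11e-04 (Npy5r), and several controls, such as Gdnf at 8.15 ± 0.0155, sat at the low end of the scale, so that the size of their rise depends on the floor.

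The 15 genes with the largest fall were mostly genes of myelin and its lipids. After Ncmap (SE of the difference 0.175), the differences were -4.20 for Pllp (SE 0.111), -4.18 for Fa2h (SE 0.128), -4.06 for Pmp2 (SE 0.138) and -4.06 for Drp2 (SE 0.127). Fa2h hydroxylates the fatty acids of myelin lipids, and Drp2 belongs to the dystroglycan complex of the Schwann cell surface. Fam178b, Ddn, Kcnk1, Mlip, Septin3 and Sptb fell, with differences from -3.90 (Fam178b) to -3.46 (Sptb), and Kcnk1 encodes a potassium channel. Gldn, which clusters channels at nodes of Ranvier, fell by 3.45. The adhesion molecule gene Mag was at -3.19, Ugt8a, the galactosyltransferase of myelin galactolipids, at -3.15, and Fdps at -3.15. Their limma adjusted p ran from 3.95e-06 (Pllp, Ddn and Mlip) to 1.98e-05 (Fam178b).

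Of 21 measured myelin protein genes, 19 fell, 0 rose and 2 were not called (20 lower when adjusted over the list alone), with a median of -1.34. The camera adjusted p was 2.14e-14, and 0.132 with an estimated correlation. Besides Ncmap, Pllp, Fa2h and Pmp2, the tight junction gene Cldn19 went from 11.81 to 8.80 and Cd9 from 15.25 to 13.34. The genes not called were Dhh, at 13.11 in mutants and 13.23 in controls, and Jam3. Probes of the most abundant transcripts fell by unequal amounts. The brightest Mbp probe, at 15.79 in controls near the top of the scale, fell by 1.33, while 3 further Mbp probes were at -3.19, -4.00 and -3.41 and a dim probe at -0.10. Both Pmp22 probes fell, the brighter at -1.21 and the other at -2.54.

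All 18 measured genes of cholesterol synthesis fell (18 when adjusted over the list alone), with a median of -1.58 (camera adjusted p = 1.78e-14, and adjusted p = 0.144 with an estimated correlation). Fdps, Msmo1, Cyp51 and Nsdhl, enzymes along the path from farnesyl diphosphate to cholesterol, were at -3.15, -2.70, -2.67 and -2.38. Srebf2, the transcription factor of the pathway, was among the genes that fell, with a difference of -0.68. Of 18 measured genes of fatty acid synthesis, 12 fell and 2 rose (14 and 2 when adjusted over the list alone), with a median of -0.64 (camera adjusted p = 1.34e-04, and adjusted p = 0.464 with an estimated correlation). Acss2, which activates acetate, fell by 2.80. The elongase genes Elovl6 and Elovl1 were at -2.40 and -1.76 and the desaturase gene Scd2 at -1.52. Elovl5, another elongase, and Gpam were the members that rose.

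**Figure D2:**
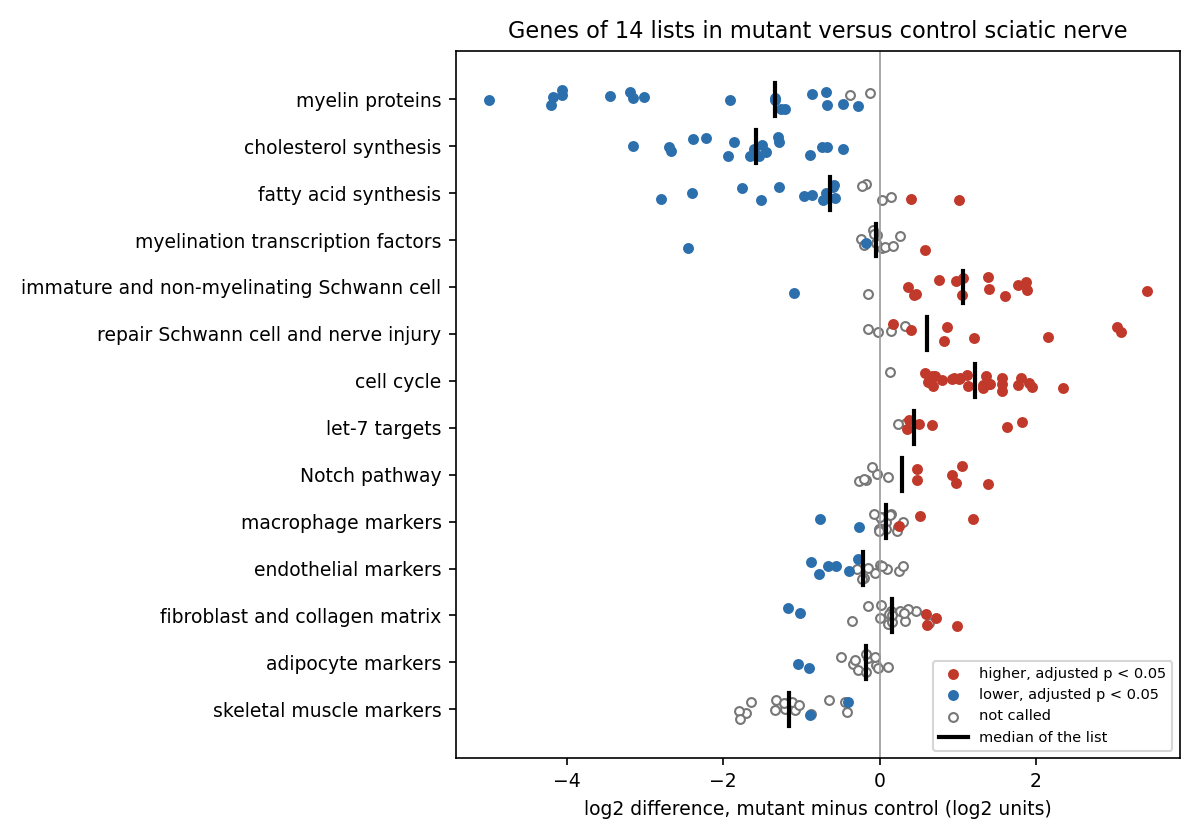
Difference of mutant minus control on the log2-like scale (horizontal axis) for each measured gene of 14 gene lists (vertical axis), with red points for genes called higher, blue for genes called lower, open points for genes not called, and a black bar for the median of each list. The medians are -1.34 for myelin proteins, -1.58 for cholesterol synthesis, 1.06 for immature and non-myelinating Schwann cell genes and 1.22 for the cell cycle.

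Of 13 measured transcription factors and cofactors of myelination, 1 rose, 2 fell and 10 were not called (1 and 2 over the list alone), with a median of -0.05. The list was not called against other genes (camera adjusted p = 0.626), but fry, which tests it against no change, gave an adjusted p of 0.0278. Egr2 fell by 2.45 (SE 0.095, limma adjusted p = 1e-05) and the deacetylase gene Hdac2 rose by 0.58. A dim Hdac2 probe, with a mean of 8.62, was not called (-3.55e-05, SE 0.072). Nab2, an Egr2 cofactor near the low end of the scale, fell by 0.17, a call lost with the replicate block (adjusted p = 0.0719), which leaves 1 gene lower, and without any single array except mutant replicate 1 (0.0542 to 0.0928). Sox10 differed by 0.04 (SE 0.070) and Pou3f1, which acts before Egr2, by -0.24 (SE 0.150), and neither was called.

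Of 16 measured genes of immature and non-myelinating Schwann cells, 14 rose and 1 fell (14 and 1 over the list alone), with a median of 1.06 (camera adjusted p = 2.72e-06, and adjusted p = 0.0774 with an estimated correlation). After Ngfr the largest were the endothelin receptor gene Ednrb at 1.89, the cyclin gene Ccnd1 at 1.87 and Id4 at 1.77. Sox2 and Jun, both opponents of myelination, rose from 8.58 to 9.35 and from 9.42 to 9.79. Scn7a, a sodium channel gene, was the member that fell, from 9.62 to 8.52. Of 12 genes of repair Schwann cells and nerve injury, 8 rose and 0 fell (9 and 0 over the list alone), with a median of 0.61 (camera adjusted p = 1.52e-04, and adjusted p = 0.111 with an estimated correlation). Tnc and Gdnf led it, followed by the engulfment receptor gene Megf10 at 2.16 and the stress-induced transcription factor gene Atf3 at 1.21. The brightness filter kept 16 of the 21 genes of immature and non-myelinating Schwann cells on the array and 12 of the 20 of the injury list. Gdnf, at 8.15 in controls, passed it through the mutant arrays.

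The cell cycle list moved as a whole, with 25 of 26 measured genes higher and 0 lower (25 over the list alone) and a median of 1.22. It was the list with the smallest camera adjusted p (2.48e-15) and the only one called with an estimated correlation (adjusted p = 0.0361). Prc1 and Plk1, which act in cell division, rose by 2.35 and 1.95, Nusap1 by 1.92 and the topoisomerase gene Top2a by 1.82. Pcna was the member not called. Of 16 cell cycle inhibitors and p53 targets, 9 rose and 2 fell (10 and 3 over the list alone), with a median of 0.35 and a camera adjusted p of 0.0541 (0.464 with an estimated correlation). This p was 0.0247 without mutant replicate 1 and 0.0499 without control replicate 3. Cdkn1a, the p21 inhibitor, fell by 2.13 (SE 0.148), and Cdkn1c, Cdkn2b and Ccng1 rose by 1.46, 1.41 and 1.19.

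Of 12 Notch pathway genes, 6 rose and 0 fell (6 and 1 over the list alone), with a median of 0.29 and a camera adjusted p of 0.0827. With the replicate block, and without mutant replicate 2, 1 gene was called lower. The receptor gene Notch1 rose by 1.39 and the target genes Hey2, Hes1 and Hey1 by 1.05, 0.97 and 0.93. Of 19 genes of axon-glia signalling and the basal lamina, 9 rose and 2 fell (9 and 2 over the list alone), with a median of 0.17 (camera adjusted p = 0.105). The basement membrane genes Nid1 and Lama2 rose by 1.44 and 0.91 and the adhesion receptor gene Adgrg6 by 0.94, while Cadm3, an adhesion molecule of axons, fell by 0.98. Of 15 genes of the unfolded protein and stress response, 4 rose and 2 fell (5 and 2 over the list alone), with a median of 0.16 (camera adjusted p = 0.416). The chaperone genes Pdia4, Hsp90b1 and Calr rose by 1.16, 0.75 and 0.54 and Asns fell by 0.56, and 1 gene was lower in each fit without an array except that without mutant replicate 1. Of 13 immediate early genes, 3 rose and 0 fell (3 and 0 over the list alone), Egr1 by 2.12 (SE 0.217), Fosl2 by 0.91 and Junb by 0.46, with a median of 0.07 (camera adjusted p = 0.392).

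Genes of the small RNA pathway and targets of small RNAs were set beside the genotype. Of 14 measured genes of the small RNA pathway, 6 rose and 0 fell (6 and 0 over the list alone), with a median of 0.12. The camera adjusted p was 0.0541, or 0.543 with an estimated correlation, and 0.0344 without mutant replicate 2. The silencing cofactor gene Tnrc6a rose by 1.55, Ago2, which carries the guide RNA, by 0.94, and Ddx17 and Tarbp2 by 0.36 each. Another Tnrc6a probe was called at 1.51 and another Ago2 probe at 0.58. The dimmest probe of each was not called, at 0.29 (SE 0.467) for Tnrc6a and 0.19 (SE 0.116) for Ago2 (limma adjusted p = 0.673 and 0.257). Without control replicate 1 or 2, 3 genes of this list were called higher, and without mutant replicate 3, 1 was called lower. The Ddx17 call was lost without control replicate 1 (adjusted p = 0.0612), 2 (0.0623) or 3 (0.0912). Of 8 measured let-7 targets, 6 rose and 0 fell (6 and 0 over the list alone), with a median of 0.45 (camera adjusted p = 0.00214, and adjusted p = 0.17 with an estimated correlation). The cyclin gene Ccnd2 rose by 1.83, Igf2bp3 by 1.63, Nras by 0.67 and Plagl2 by 0.51. The dimmest probes of Igf2bp3 and Nras were not called, at 0.13 and 0.07 (limma adjusted p = 0.142 and 0.47). The array held 14 let-7 targets, of which the brightness filter kept these 8. Of 11 genes of the imprinted growth network, 3 rose and 0 fell (3 and 0 over the list alone), namely Grb10 by 1.61, Cdkn1c, and Igf2r by 0.28, with a median of 0.08 (camera adjusted p = 0.338). The Igf2r call (adjusted p = 0.0325) was lost without mutant replicate 2 (0.0982) or 3 (0.0834) and without control replicate 1 (0.093) or 3 (0.104).

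Of 18 macrophage markers, 3 rose and 2 fell (3 and 2 over the list alone), with a median of 0.08 (camera adjusted p = 0.518). Mpeg1 rose by 1.19 and Laptm5 by 0.51, while Cd163 and Cd14 fell, at -0.76 and -0.26. Without mutant replicate 1, 7 were called higher, and without control replicate 1 or 2, where the Cd14 call was lost (adjusted p = 0.0757 and 0.0726), 1 was called lower. Of 5 measured markers of T cells, B cells and mast cells, 4 rose and 0 fell (4 and 0 over the list alone), with a median of 0.71 (camera adjusted p = 0.0431, and adjusted p = 0.464 with an estimated correlation). All 4 are mast cell genes, the protease genes Cpa3 (1.04), Cma1 (1.04), Mcpt4 (0.71) and Tpsb2 (0.60), and the list's call was lost without mutant replicate 3 (adjusted p = 0.0515), without control replicate 1 (0.0558) and with a stricter brightness filter (0.0535). Of 11 genes of antigen presentation, 1 rose and 2 fell (1 and 2 over the list alone), with a median of 0.05 but a mean of -0.36, and the test pointed down (camera adjusted p = 0.589). The median was -0.19 without control replicate 1 and 0.19 without control replicate 3. H2-DMa and H2-DMb1, which load peptides on class II molecules, were lower, at -2.94 and -2.73, and the peptide transporter gene Tap2 rose by 0.97. Of 13 interferon response genes, 2 rose and 0 fell (2 and 0 over the list alone), Rsad2 by 0.65 and Ddx58 by 0.35, with a median of -0.09 (camera adjusted p = 0.518). That median was -0.30 without control replicate 1 and 0.03 without control replicate 3. With the replicate block 3 were called lower. Without control replicate 1 this list had 1 higher and 2 lower, without control replicate 2 it had 0 higher, and without mutant replicate 3 it had 1 higher. Rsad2 was the gene that lost its call without mutant replicate 3 (adjusted p = 0.0549) and control replicate 1 (0.0777), and both genes did without control replicate 2 (0.0787 and 0.0537). Of 10 neutrophil markers on the array, 1 passed the brightness filter. It was Retnlg, which passed through the mutant arrays, with 9.03 in mutants and 8.20 in controls. It rose by 0.83 (limma adjusted p = 0.0269). That call was lost in every fit that left out an array (adjusted p from 0.0569 to 0.0832) except the fit without mutant replicate 1. With all probes tested, Retnlg was not called (limma adjusted p = 0.08), while Lcn2, a marker left out by the filter, was called lower, at -0.23 (8.75e-04). These values give no direction for neutrophil markers.

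Stromal and vascular markers were mixed. Of 21 fibroblast and collagen matrix genes, 4 rose and 2 fell (4 and 2 over the list alone), with a median of 0.17 (camera adjusted p = 0.204). Lum and Postn rose by 0.99 and 0.72, and the small proteoglycan gene Ogn and the crosslinking enzyme gene Lox fell, at -1.17 and -1.01. Of 6 perineurial markers, 2 rose and 1 fell (2 and 1 over the list alone), with a median of -0.06 but a mean of 0.64 set by Krt23, and the test pointed up (camera adjusted p = 0.626). Itgb4 rose by 0.48 and Tjp1 fell by 0.33, and 2 were lower without mutant replicate 1 or 3. Of 16 endothelial markers, 6 fell and 0 rose (6 and 0 over the list alone), with a median of -0.21. The camera adjusted p was 0.72 with an estimated correlation and 0.0653 with the preset. The p was 0.0491 with the replicate block, where 2 were called higher, 0.046 without mutant replicate 1 and 0.008 without control replicate 3. Cldn5, Egfl7, Ly6c1 and Vwf fell, at -0.88, -0.78, -0.65 and -0.55, though the dimmest Egfl7 probe was not called, at -0.06 (limma adjusted p = 0.454). In the list, 3 were lower without mutant replicate 2, mutant replicate 3 or control replicate 1, where the Vwf call was among those lost (adjusted p = 0.0505, 0.057 and 0.0667). Of 11 pericyte and smooth muscle markers, Pdgfrb rose by 0.36 and Kcnj8 fell by 0.24 (1 and 0 over the list alone), with a median of -0.09 (camera adjusted p = 0.707). That median was -0.30 without control replicate 3 and -0.001 without control replicate 2. Kcnj8 passed in none of the fits without mutant replicate 1, 2 or 3 or control replicate 1 or 2, and 3 of the list were lower without control replicate 3.

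Markers of neighbouring tissue differed between single arrays. The median of 18 skeletal muscle markers was 12.34 in control replicate 2 and 9.06 in mutant replicate 3, and between 10.64 and 10.87 in the other 4 arrays. The list had a median of -1.15 and a camera adjusted p of 0.00364 (0.72 with an estimated correlation), but 2 of its genes fell (1 over the list alone), with Myh1 at -0.89 and Mb at -0.40. With the replicate block 9 fell, without mutant replicate 1 there were 6, and without mutant replicate 2 or 3 or control replicate 2 or 3 there was 1, the Mb call being lost there (adjusted p from 0.0669 to 0.0903). The median was -0.54 without mutant replicate 3 and -0.75 without control replicate 2. Of 13 adipocyte markers, 2 fell (2 over the list alone), the brown fat genes Ucp1 at -1.04 and Cidea at -0.91, with a median of -0.18 (camera adjusted p = 0.0381, and adjusted p = 0.661 with an estimated correlation). The median was -0.29 without mutant replicate 1. The call was lost without mutant replicate 3 (adjusted p = 0.108), without control replicate 2 (0.0722) and with a stricter brightness filter (0.0604, with a median of -0.29). The block called 4 lower, and 5 were lower without mutant replicate 1 or control replicate 3. Of 5 neuronal and axonal markers, 2 fell (2 over the list alone), Syn1 at -0.31 and Uchl1 at -0.25, with a median of -0.02 (camera adjusted p = 0.428), and at most 1 was lower in any fit without an array. Syn1 lost its call without mutant replicate 2 or 3 or control replicate 1 (adjusted p from 0.0544 to 0.0714), and Uchl1 without any single array except mutant replicate 3 (0.0514 to 0.137). None of 4 red blood cell markers was called in limma (0 over the list alone), with Hbb-bt at -0.43 and Hba-a1 at -0.53, though both fell without mutant replicate 3 (adjusted p = 0.0124 and 0.0125). None of the 3 sex-linked genes was called (0 over the list alone), with Xist at -0.23, Kdm5d at 0.00 and Uty at 0.02, and the camera adjusted p was 0.518 for the red blood cell list and 0.89 for this one. Xist varied within the groups, at 10.84, 9.58 and 9.63 in mutant replicates 1 to 3 and 10.76, 10.43 and 9.54 in control replicates 1 to 3. Kdm5d and Uty lay between 8.54 and 8.90 in all arrays. Whether the arrays differ in their mix of sexes was not tested.

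Arrays were also set apart by 3 gene groups chosen after the data were seen. These groups may reflect RNA state, but no measure of RNA quality was used here. The median of 53 ribosomal protein genes was 12.71 in mutant replicate 1 and between 13.58 and 13.69 in the other 5 arrays. The median of 12 H2A histone genes was 11.32 in mutant replicate 1, 12.33 in mutant replicate 2, 13.32 in mutant replicate 3 and 12.10 to 12.24 in controls, so that mutant replicates 1 and 3 lay on opposite sides. Of these 12 genes, near copies whose values are uncertain as separate genes, 3 rose and 2 fell. Without mutant replicate 1, 9 rose and 2 fell, without mutant replicate 3, 2 rose and 2 fell, without mutant replicate 2, 0 rose and 2 fell, and without any single control array 0 rose and 1 fell. With cyclic loess 0 rose and 2 fell. The median of 70 respiratory chain genes was 11.02 in mutant replicate 1, 11.86 and 11.80 in the other mutant arrays and 12.09 to 12.19 in controls. Of these 70 genes, 20 fell and 1 rose. Without mutant replicate 1, 42 fell and 2 rose, with a median change of -0.32 against -0.58 over all arrays. The number that fell was 35 without mutant replicate 3, 9 without mutant replicate 2, and 5, 5 and 7 without control replicates 1, 2 and 3. Without mutant replicate 1 the myelin list had 19 genes lower with a median of -1.45, the cholesterol list 18 with a median of -1.58, and the cell cycle list 25 genes higher with a median of 1.19. Without mutant replicate 3 these lists had 19, 18 and 25, with medians of -1.43, -1.62 and 1.23. The list of immature and non-myelinating Schwann cells had 14 genes higher without either array. The injury list had 9 without mutant replicate 1 and 7 without mutant replicate 3.

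**Figure D3:**
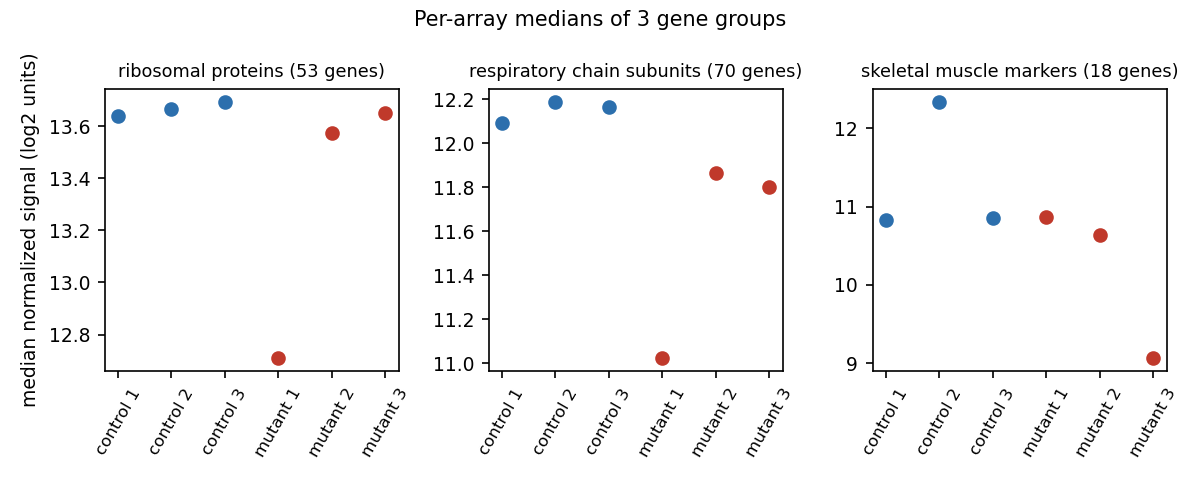
Median normalized signal on the log2-like scale (vertical axes, each with its own range) of ribosomal protein, respiratory chain and skeletal muscle genes in each control array (blue) and mutant array (red). Mutant replicate 1 is lowest for ribosomal protein genes (12.71) and respiratory chain genes (11.02), and mutant replicate 3 is lowest for muscle markers (9.06).

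Across the 28 lists tested, 10 were called by camera at an adjusted p under 0.05, and 1 with an estimated correlation. Other splits of the 6 arrays into 3 and 3 gave 4 to 16 called lists at the preset, so the number 10 alone does not mark the genotype. The estimated correlation was 0.21 for the myelin list and 0.309 for the cholesterol list, above the preset 0.01. It was -0.017 for the list of immature and non-myelinating Schwann cells and -0.011 for the injury list, below the preset, and all 4 lost their calls. That version of the test also uses the 4 residual degrees of freedom of the arrays. fry, which does not compare a list with other genes, called 15 lists. Besides that of the myelination transcription factors, the lists it called and camera did not were the perineurial markers (adjusted p = 0.000365), the cell cycle inhibitors and p53 targets (0.00136), the Notch pathway and the small RNA pathway (0.0036 each), axon-glia signalling and the basal lamina (0.00584) and the unfolded protein and stress response (0.0062). Of the 6 perineurial markers 2 rose and 1 fell, and of the 13 myelination factors 10 were not called. For these lists the fry call does not mean that the list moved as a whole. The adipocyte markers (0.0785) and the skeletal muscle markers (0.154) were not called by fry. Tested without the brightness filter, Ddx17, Igf2r, Rsad2, Retnlg, Vwf, Kcnj8, Mb, Syn1 and Uchl1 lost their calls (limma adjusted p from 0.0583 to 0.0883). With the muscle marker median as a covariate, chosen after the data were seen, the calls of Asns, Junb, Ogn, Lox, Cd14, Ddx58, Rsad2, Igf2r, Nab2, Vwf, Mb, Retnlg, Kcnj8, Uchl1 and the dimmer Dicer1 probe were lost (0.0509 to 0.244), though their differences still had 59.4% (Kcnj8) to 124.9% (Uchl1) of their size without it, and Hbb-bt and Hba-a1 were called (0.0125 and 0.00374). The lists of T cell, B cell and mast cell markers, adipocyte markers and skeletal muscle markers also lost their camera calls with that covariate (adjusted p = 0.0703, 0.227 and 0.122). Their medians then had 78.7%, 57.5% and 7.7% of their size without it.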

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

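The probes that the brightness filter left out also held differences between the groups. When all probes were tested together with limma, 536 of the 26861 left-out probes were called, 311 higher and 225 lower in mutants. Their changes were at most 0.54 in size, but a filter on the mean over all arrays, at 8.34 on a scale that starts at 7.96, itself limits the size a change can have among them. Lingo3 led them, with 8.58 in mutants and 8.04 in controls, followed by Hmga2, a let-7 target, with 8.58 and 8.08. The kinase gene Melk, active in dividing cells, rose by 0.38 and Cdc25c, a phosphatase that starts mitosis, by 0.38, while Hecw2 fell by 0.41. These genes were chosen after their values were seen.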

How the results depend on the processing

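Cyclic loess, the covariates and the counts without single arrays were chosen after the data were seen. The number of probes called stayed within 1.5 times of 6596 in every alternative run for it: 6287 with the replicate block, 6386 without a filter, 4901 with a stricter brightness filter, 9736 with array weights and 5172 with the muscle marker covariate. Leaving out each array gave 4598 to 7502 probes called, 789 to 948 called at least 2-fold and 8 to 12 lists called. The block gave 841 probes at least 2-fold and 11 lists, and apart from the calls and counts named in the report it changed no other call of a named gene or list. Centring the arrays and quantile normalizing again left the values as they were and test nothing. The count at 2-fold moved from 828 to 2344 with a threshold of 1.5-fold and to 2381 with treat against 1.2-fold, since both let smaller changes in. The lists called moved from 10 to 1 with an estimated correlation, by the construction of that test, which uses the few residual degrees of freedom of the arrays and each list's own correlation, which lay below the preset for 2 of the lists that lost their call. With fry 15 were called, but fry does not compare a list with other genes. No result reversed. Of the 116 named genes (Dicer1 by its dimmer probe), 96 kept their call or its absence in every alternative run for them, as did 11 of 28 lists. Over all alternatives, gene results lost a call 81 times and gained one 7 times, and list results 20 and 22 times. Besides the calls lost that the report names, Uchl1 lost its call with the stricter filter (adjusted p = 0.0562) and the ribosomal protein covariate (0.0674), Ddx17 with an intensity trend (0.0641) and cyclic loess (0.0551), Kcnj8 with an offset (0.0528) and the dimmer Dicer1 probe with the ribosomal protein covariate (0.0621). Xist (0.0405), Hbb-bt (0.0226) and Hba-a1 (0.015) were called with array weights. Cell cycle inhibitors were called without a filter (0.0131), with array weights (0.0282) and the ribosomal protein covariate (0.0222), endothelial markers without a filter (0.0441) and with that covariate (0.0379), the small RNA pathway without a filter (0.0102), with the stricter filter (0.0498) and with probe means (0.0401), and axon-glia signalling with the stricter filter (0.045). Of the 828 probes called at least 2-fold, 734 were also called without mutant replicate 1 and 798 without mutant replicate 3, all in the same direction. Signal over background limits the dim end: the lowest kept mean was 8.34.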

Other observations

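All genes and gene groups in this paragraph and the next were chosen after their values were seen. Of 34 measured collagen genes, 10 rose and 4 fell, with a median of 0.14, and the group was not called against other genes (camera adjusted p = 0.14 over this group and the next, and 0.505 with an estimated correlation). Col9a3 rose by 2.19, Col2a1 by 1.26 and Col8a1 by 1.24 beside Col18a1 at 2.55, while Col23a1, a transmembrane collagen, fell by 3.00 (limma adjusted p = 3.95e-06). Of 22 measured potassium channel genes, 7 rose and 7 fell, with a median of -0.13 (camera adjusted p = 0.796, and adjusted p = 0.79 with an estimated correlation), and 4 fell without mutant replicate 2 or 3 or control replicate 1 or 2. Kcnk1 fell by 3.67 and Kcna2, a channel of the juxtaparanode, was at -0.82, while Kcnh2 rose by 2.77 and Kcnk5 by 1.41. The guidance gene Sema5a fell by 2.70, Slit2 and Ntn5 were lower, at -2.62 and -2.22, and Efna5 rose by 2.37. The metallothionein genes Mt3 and Mt1 fell, at -2.37 and -1.27, as did the complement regulators Cd59a and Cd59b, at -1.38 and -1.54. Cd59a and Cd59b are near copies and are reported as uncertain.

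Gfra3 rose by 2.76, while Ret, its signalling partner, differed by 0.00 (SE 0.165) and Gfra1, the co-receptor for Gdnf, by 0.08 (SE 0.097). Of the 3 neuropeptide Y receptor genes measured, Npy5r rose by 2.66 and Npy1r by 1.28, and Npy6r, near the low end of the scale, fell by 0.44. Dct and Rab38, which act in pigment cells, rose by 1.51 and 1.87, but Pmel, another pigment cell gene, fell by 0.74. Beside Ucp1 and Cidea, the heart, muscle and brown fat genes Cox8b, Cox7a1 and Slc36a2 fell, at -1.77, -1.52 and -1.27, while Adipoq, a general fat marker, differed by -0.50 (SE 0.173, limma adjusted p = 0.0656) and was not called. The median of skeletal muscle markers was highest in control replicate 2 (12.34) and lowest in mutant replicate 3 (9.06), so a part of muscle content in these falls stays open.

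All tests below were chosen after the results were seen. The fall of the myelin genes (median -1.34) was set against a loss of Schwann cells and against the RNA state of mutant replicate 1. A loss of Schwann cells with no other change would lower their lineage genes outside the myelin list too, but the lower of Sox10 and Cdh19, Sox10, changed by 0.0355 and, less 2 SE, lay at -0.10, where a fall to -0.67 was needed. Cdh19, at 0.98, belongs to the list of immature and non-myelinating Schwann cells. A loss of cells offset by a higher output of such genes in the remaining cells was therefore not tested and stays open. Without mutant replicate 1 the myelin median was -1.45, which argues against the state of that RNA as the cause. The mutant genotype acting within Schwann cells also stays open, and counts of Schwann cells, which were not used here, would bear on both.

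Respiratory chain genes had a median change of -0.58 over 70 genes, and without mutant replicate 1 it was -0.32, 54.9% of the full change and beyond the 0.098 range of the control medians, and 42 genes were called lower, against 20 with all arrays. This argues against the state of that RNA as the whole cause, and its part in the size of the change stays open. The number called lower was 35 without mutant replicate 3, 9 without mutant replicate 2, and 5 to 7 without a control array. With the muscle marker median as a covariate, 24 genes were called lower (15 of the 20) with a median of -0.77. Without mutant replicate 1 as well, 31 were, fewer than the 42 without the covariate. In those arrays the medians differed by -0.26 with the covariate (95% interval -0.46 to -0.05). For those arrays an interval below 0 is not what a lower muscle content as the whole cause would give. But with the covariate the median change of the genes grew in size, from -0.32 to -0.36 there and from -0.58 to -0.77 over all arrays. The covariate may therefore not track muscle content alone, and the test does not decide on that cause. The part of muscle content stays open, as does the genotype. Over all 6 arrays the interval with the covariate was wide (-0.73, 95% interval -1.91 to 0.44), and 6 and 5 genes were called lower with it without control replicates 1 and 3.

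H2-DMa, H2-DMb1 and H2-DMb2 were lower, at -2.94, -2.73 and -2.69, and the latter pair are near copies, so their values are uncertain as separate genes. Fewer antigen-presenting cells would lower the other class II genes, but H2-Aa, H2-Ab1, H2-Eb1 and Cd74 had a median change of -0.0245, and none, less 2 SE, went below -0.83, where -1.37 was needed. Another haplotype of this region carried with the mutant genotype could lower probe binding. Of the 40 nearest measured genes, 37.5% were called, against 39.6% of all genes (1-sided Fisher's exact p = 0.663), and neighbours called no more often than other genes exclude no sequence variant, so haplotype and genotype cannot be told apart.

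The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 6596 probes called and 828 called at least 2-fold, the highest of the others gave 0 and 0 in limma, and 1 of the 10 splits, the real one, gave as many. At an unadjusted p under 0.05 the other splits had 76 to 542 probes and the real one 8368. For lists called, 4 of the 10 splits gave at least the 10 of the real one, and the highest other gave 16. The 3 other splits that part all 3 same-numbered pairs gave 0 probes and 4, 8 and 8 lists. Each other split still sets 2 arrays of a genotype against 1, so it holds part of the real difference. Whether that part accounts for the lists called in these splits was not tested. The number of lists called at the camera preset therefore does not set the real split apart.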
